A study of Danio rerio with 6 samples.

How the data were processed

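Poly-A selected RNA from larval zebrafish was sequenced from 6 libraries, 3 of sirt6 mutants and 3 of wild type, all at 3 days post fertilisation. Per the labels' protocols, larvae were sorted by genotype, RNA was taken from tails with their blood-forming tissue by TRIzol extraction, and libraries were made with a Novogene kit. Per the submitters' processing notes, FastQC, HISAT2 2.0.5, featureCounts and DESeq2 were used with the GRCz11 build. The annotation release, the strand setting of the counting and the filters are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart.

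The authors deposited FPKM values, that is, fragments scaled by gene length and library size, with the gene length and position in the same table. No genome sequence was used here. The table lists 38157 genes, and 5741 of them have no symbol. Alternate contigs, which hold second versions of some genome regions, carry 3772 of the genes, so reads from such regions can be split between copies. No column of values per sample was left unused.

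Each deposited FPKM value, multiplied by gene length, was a whole multiple of 1 unit per library within a tolerance of 1e-06 for 100% of the values above 0. Reads per gene were recovered from this. Reads in genes numbered 14655293, 13544132 and 12438359 in wild-type libraries 1, 2 and 3, and 12788974, 14314865 and 13970013 in mutant libraries 1, 2 and 3. The library sizes implied by the deposited values lay within a factor of 0.952 to 1.06 of these totals, so the values were not scaled by these totals alone.

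The main test used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a variance trend on mean level, for the 23855 genes with a mean of at least 0.5 FPKM over the 6 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A log2 fold change is the mutant mean minus the wild-type mean on this scale, and the added 0.5 understates the change of genes of low level. The labels do not say that the replicates came from separate pools of larvae, so the p-values measure the spread between these samples, which may be technical. Exact permutation tests of 3 against 3 libraries cannot give a p below 0.1.

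The design, the alternatives, the rule for named genes and 42 gene lists were chosen before the data were examined. The lists cover blood and other cell types of the tail, organs outside it, and processes that SIRT6 has been tied to. They were tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated for each list, and with fry, for lists with at least 5 tested genes. Named genes were the sirtuins and, for each direction, the 10 genes of largest change among those passing, with a symbol that is not a clone name, a mean of at least 1 FPKM and no overlap between genotypes. Places left empty went to genes of smallest p in that direction, given as not passing. Up to 4 genes of smallest p were added for each list that passed camera, and up to 3 passing genes for any other list.

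The fit was tested on simulated data made from the means and spreads of these libraries, with 3 against 3 libraries and 23792 genes tested. It called 14% of the genes changed 2-fold and 62% of those changed 4-fold, with 3 false calls among 79. Each gene was drawn independently, so differences between libraries that many genes share were not simulated. These shares may thus not carry over to the data.

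Alternatives changed the pseudocount to 0.1 or 1, the filter to none or to a mean of at least 5 FPKM, the scaling to median-of-ratios or quantile normalization, the variance model, and the threshold to include an absolute log2 fold change of at least 1. Further alternatives added the replicate number as a block, ran limma voom on the recovered reads, or left out each library in turn. Others were added after the data had been seen. They left out 2 libraries together, weighted libraries by quality, adjusted for gene length, left out alternate contigs, or summed the closest pairs of libraries. The position of the sirt6 lesion is not given in the sources used here, and zygosity was not analysed here.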

Results

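The study asked how loss of sirt6 affects gene expression in zebrafish larvae. The gene encodes a NAD-dependent deacylase that acts on histones, and a mutant line was made with CRISPR/Cas9. RNA-seq gave FPKM values for tails of sirt6 mutant and wild-type larvae at 3 days post fertilisation, with 3 libraries per genotype. Of the 38157 genes listed, 31772 had a value above 0 in at least 1 library. Reads in genes ranged from 12438359 to 14655293 per library.

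The 6 libraries did not split by genotype alone. Wild-type libraries 2 and 3 lay close together, with a Pearson r of 0.975 across genes and a chi-square per degree of freedom of 2.9 on recovered reads. Mutant libraries 1 and 3 were also close, with an r of 0.977 and a chi-square per degree of freedom of 3.5. The other 13 pairs had values of 15 to 38, and genes are not independent replicates in either measure. Wild-type library 1 and mutant library 2 carried more reads of short genes, with median deviations from the mean of all libraries of 0.27 and 0.19 on the log2 scale. In the other 4 libraries this deviation lay between -0.15 and -0.07. Transcripts of cytosolic ribosomal proteins deviated by 0.59 in wild-type library 1 and by 0.29 in mutant library 2, against -0.31 to -0.12 in the others.

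The targeted gene, sirt6 (ENSDARG00000102963, GRCz11 chromosome 2, 53065039 to 53201840), was read first. Its level was 3.85 ± 1.78 FPKM (SD, n = 3) in wild type and 3.32 ± 0.251 FPKM (SD, n = 3) in mutants. The log2 fold change was -0.11 with a 95% interval of -0.75 to 0.52, and the exact two-sided permutation test gave p = 0.9, where 0.1 is the smallest p possible. Without wild-type library 1, which had 5.85 FPKM, the log2 fold change was 0.20. Each library held 50 to 131 reads of sirt6. The position of the lesion was not known here, so the transcript level does not check the genotype labels. None of the other sirtuins passed limma in the main test. Without wild-type library 1 and mutant library 2 sirt2 passed as lower (log2 fold change -0.313, adjusted p = 0.0299), and it did so with library weights (-0.283, adjusted p = 0.0325), in a range of 0.0299 to 1. In these fits 4429 and 4849 of 23855 genes passed limma. The libraries left in the first fit are the close pairs, so it cannot separate genotype from pair. The weights were lowest for the libraries that the first fit left out, so the second fit is no separate support. The level of sirt1 was 5.98 ± 0.40 FPKM in wild type and 5.30 ± 0.354 in mutants, sirt2 24.2 ± 1.46 and 20.7 ± 1.21, and sirt7 0.885 ± 0.328 and 1.2 ± 0.154 (SD, n = 3 each). The corresponding values were 1.49 and 1.3 for sirt3, 3.86 and 3.33 for sirt4, and 8.18 and 7.46 for sirt5.

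The neutrophil genes npsn and mpx and the retinal gene saga were among the genes that separated mutant from wild-type libraries with the smallest p on the higher side, and the chemokine gene cxcl8a and the glucokinase gene gck on the lower side, but no single gene passed the test over all genes. Of the genes taken by the naming rule, which leaves out clone names, saga had the smallest p. It encodes an arrestin of the retina (chromosome 2, 5480125 to 5505094), at 6.09 ± 0.209 FPKM in wild type and 14.8 ± 0.544 in mutants (SD, n = 3). Its log2 fold change was 1.21 (SE 0.12, limma adjusted p = 0.128). The metalloprotease gene npsn stood at 13.7 ± 0.643 and 26.6 ± 1.37 FPKM, and mpx, the myeloperoxidase, at 11.3 ± 0.238 and 19.6 ± 0.724 (limma adjusted p = 0.183 and 0.242). The glucokinase gene gck stood at 11.9 ± 3.96 FPKM in wild type and 3.65 ± 0.519 in mutants, with a log2 fold change of -1.55 (SE 0.23, limma adjusted p = 0.221).

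With limma, 0 genes passed as higher and 0 as lower among 23855 tested, and the smallest adjusted p was 0.0679, that of si:ch1073-429i10.1. At an unadjusted p under 0.05 there were 1368 genes, 585 higher and 783 lower in mutants, where 1193 would be expected by chance. With limma voom on recovered reads, 0 genes passed and 1232 had an unadjusted p under 0.05. The libraries of the genotypes did not overlap for 2518 genes, or 10.6% of those tested, and chance gives 10%. Without wild-type library 1 and mutant library 2, an alternative chosen after seeing the data, 2183 genes passed as higher and 2246 as lower. The libraries left there are the close pairs, so that fit cannot separate genotype from pair. With genes under a mean of 5 FPKM left out, saga and si:ch1073-429i10.1 passed as higher (limma adjusted p = 0.0402 for both), and over the alternatives that of saga ranged from 0.00188 to 0.717. The gene si:ch1073-429i10.1 is named here after its values were seen.

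The naming rule took 20 genes by smallest p, and those not given above had libraries of the genotypes apart from each other but did not pass limma, with adjusted p from 0.199 to 0.494. Of the 50 genes under the naming rule other than sirt6, 36 passed limma without wild-type library 1 and mutant library 2. These 50 include sirtuins and list members, and 38 of them passed with library weights and 35 in both fits. Over all 23855 genes tested, 4429 and 4849 passed in these fits. Most of the 50 were taken for a small p in these same libraries, so their passing is no separate support. Higher in the 3 mutant libraries were srgn, the granule proteoglycan serglycin, at 10.3 ± 2.14 FPKM against 4.70 ± 0.552 in wild type, and irg1l, an immune-responsive gene, at 8.91 ± 1.06 against 4.98 ± 0.254. The photoreceptor genes rom1b and grk1a, which encode an outer segment membrane protein and a rhodopsin kinase, stood at 11.8 ± 2.17 against 5.89 ± 0.588 FPKM and at 5.80 ± 0.388 against 3.17 ± 0.225. The complement factor H-like gene cfhl4 stood at 13.7 ± 1.52 against 7.94 ± 0.673 FPKM. The cholesterol 25-hydroxylase-like gene ch25hl2 stood at 2.87 ± 0.169 against 0.824 ± 0.144 FPKM, and MFN1, a mitochondrial fusion gene on chromosome 2 (5338759 to 5356686), at 1.92 ± 0.269 against 0.43 ± 0.0125. Reads were few, with 12 to 17 of ch25hl2 and 7 to 8 of MFN1 per wild-type library.

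Lower in the 3 mutant libraries was cxcl8a, a chemokine that attracts neutrophils, at 0.702 ± 0.0756 FPKM against 2.41 ± 0.117 in wild type (SD, n = 3), with 6 to 8 reads per mutant library. Also lower were g0s2, an inhibitor of lipolysis, at 1.47 ± 0.262 against 4.33 ± 1.11 FPKM, ch25h, a cholesterol 25-hydroxylase, at 0.323 ± 0.118 against 1.73 ± 0.498, and elovl2, a fatty acid elongase, at 3.60 ± 0.289 against 6.87 ± 1.19. Each mutant library held 4 to 7 reads of ch25h. The bile acid transporter slc10a2 stood at 2.05 ± 0.435 against 4.4 ± 0.534 FPKM, the dynein light chain gene dynlt1 at 2.21 ± 0.223 against 4.3 ± 0.0536, and lgals3bpb at 2.82 ± 0.406 against 5.24 ± 0.394. The microRNA gene dre-mir-124-2 had 4 reads in each mutant library and 8 to 14 in wild type. For dre-mir-92a-2, 0 reads in the mutant libraries and 1 to 4 in wild type were too few for a fold.

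**Figure D1:**
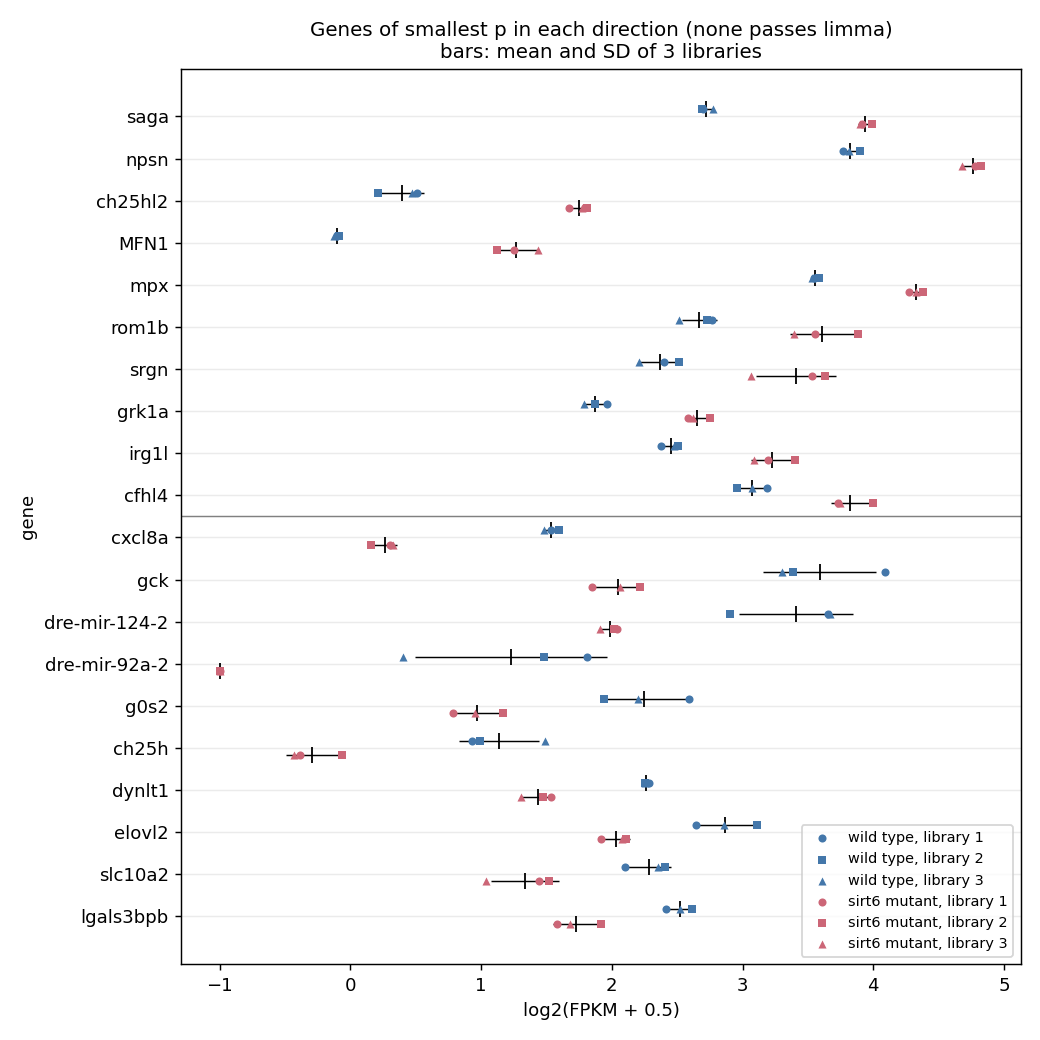
Levels of the 20 named genes of smallest p, as log2(FPKM + 0.5) on the horizontal axis, with 1 symbol per library and bars for the mean and SD of 3 libraries. The 10 upper genes are higher and the 10 lower genes are lower in all 3 mutant libraries, as the naming rule requires, and none passed limma.

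Of the 42 gene lists, 6 passed camera at the preset correlation and 0 passed with a correlation estimated for each list, where the smallest adjusted p was 0.188. The estimates were 0.376 for mitochondrially encoded genes, 0.188 for cell cycle and 0.073 for immediate early genes. For erythroid, macrophage and notochord genes they were -0.017, -0.012 and 0.005, below the preset 0.01. A higher correlation is thus not why these last lists lost their call. Adjusted over the list alone, 7 genes of 3 lists passed, 6 higher and 1 lower. With fry, 1 list passed, the erythroid genes other than globins (adjusted p = 0.00986 in limma's fry).

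Of 32 erythroid genes other than globins, 25 had lower means in mutants and 0 passed adjusted over the list alone. This list was shifted down in camera, with a median log2 fold change of -0.21 (limma adjusted p = 0.00188, and adjusted p = 0.188 with an estimated correlation). Without wild-type library 1 the erythroid median was -0.123. The heme synthesis genes hmbsb and alad stood at 5.92 ± 0.411 against 9.51 ± 2.07 FPKM and at 12.4 ± 2.18 against 17.2 ± 1.69, and hdr at 5.29 ± 0.813 against 7.97 ± 1.98, while xk was higher, at 3.72 ± 0.566 against 2.62 ± 0.335 (SD, n = 3). The macrophage list was also shifted down, with 22 of 29 genes lower, 0 passing adjusted over the list alone and a median of -0.16 (limma adjusted p = 0.00175, and adjusted p = 0.188 with an estimated correlation). It was no longer called with genes under a mean of 5 FPKM left out (median -0.157, adjusted p = 0.25, the highest of 22 alternatives, which ranged down to 0.000613), and its median was -0.247 without wild-type library 1. Its members mrc1b, a mannose receptor, and spi1b, a myeloid transcription factor, stood at 3.40 ± 0.0472 against 4.93 ± 0.862 FPKM and at 1.53 ± 0.218 against 2.23 ± 0.137. The members fcer1gl and grn2 stood at 6.93 ± 1.0 against 10.17 ± 1.97 and at 0.242 ± 0.235 against 1.72 ± 0.896. Without wild-type library 1 and mutant library 2, the erythroid list had a median of -0.162 (adjusted p = 0.0698, in a range of 0.00107 to 0.0698) and the macrophage list one of -0.24 (adjusted p = 0.0939). With library weights the erythroid median was -0.147 (adjusted p = 0.0526) and the macrophage median -0.268 (adjusted p = 0.0398).

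The neutrophil list did not pass camera (adjusted p = 0.102), with 13 of 26 genes higher and 13 lower. It passed as shifted up in 5 of 22 alternatives, where its adjusted p ranged from 0.00811 to 0.93. These were genes of a mean of 5 FPKM or more (median log2 fold change 0.102, adjusted p = 0.00811), close pairs of libraries summed (adjusted p = 0.0193), and the fits without wild-type library 2 (0.081, adjusted p = 0.0362), mutant library 1 (0.093, adjusted p = 0.0366) or mutant library 3 (0.013, adjusted p = 0.0385). Adjusted over the list alone, npsn, mpx and srgn passed as higher, and fry's test for change in either direction gave an adjusted p of 0.00904. Embryonic globins, with a median of 0.25, did not pass as a list (adjusted p = 0.0568), but passed as shifted up in 9 of 22 alternatives, with medians from 0.076 without mutant library 2 to 0.516 without wild-type library 1 and adjusted p from 0.000929 to 0.663. These included no filter (adjusted p = 0.0155), quantile normalization (adjusted p = 0.0167), the replicate block (adjusted p = 0.0434) and the fits without wild-type library 1 (adjusted p = 0.00319), mutant library 1 (0.316, adjusted p = 0.00611) or mutant library 3 (0.361, adjusted p = 0.00688). The globin gene hbbe3 passed as higher adjusted over the list alone, at 1.91 ± 0.175 FPKM against 0.476 ± 0.309 (SD, n = 3). Genes of haematopoietic stem and progenitor cells had a median log2 fold change of 0.01 over 20 genes (adjusted p = 0.794), those of thrombocytes and mast cells 0.01 over 13 (adjusted p = 0.878), and those of lymphoid cells -0.28 over 11 (adjusted p = 0.136). Over the alternatives these medians ranged from -0.099 to 0.09, -0.077 to 0.044 and -0.362 to -0.119, and none of these lists passed.

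Genes of notochord and cartilage were shifted up, with 24 of 28 higher in mutants, 0 passing adjusted over the list alone and a median log2 fold change of 0.24 (limma adjusted p = 8.95e-05, and adjusted p = 0.188 with an estimated correlation). The cartilage collagen col2a1a stood at 155 ± 3.42 FPKM in mutants and 122 ± 10.9 in wild type, col9a1b at 27.7 ± 3.31 and 20.8 ± 4.4, col11a2 at 54.6 ± 9.43 and 41.3 ± 4.89, and the notochord factor tbxta at 3.75 ± 0.308 and 2.64 ± 0.475 (SD, n = 3). This list passed in each of 22 alternative fits at the preset correlation. Among these, the robust variance model and median-of-ratios rescaling gave the camera p of the main test again (2.13e-06), so they add no separate support. Median deviations of the notochord and cartilage list were 0.06, -0.20 and -0.12 in wild-type libraries 1, 2 and 3. In mutant libraries 1, 2 and 3 they were 0.15, 0.13 and 0.07. Wild-type library 1 thus lay near mutant library 3, and only the close pair of wild-type libraries 2 and 3 lay well below the mutants. All 13 protein-coding genes of the mitochondrial genome had lower means in mutants, 0 passing adjusted over the list alone, with a median of -0.37 (limma adjusted p = 0.000411, and adjusted p = 0.591 with an estimated correlation). For mt-nd3 the level was 940 ± 236 FPKM in mutants and 1551 ± 106 in wild type, for mt-atp8 89.8 ± 24 and 140 ± 10.5, for mt-nd4l 1104 ± 69.1 and 1424 ± 140, and for mt-nd6 1674 ± 534 and 2492 ± 573. Wild-type library 1 lay apart from the other wild-type libraries in this list, with a median deviation of -0.06 against 0.28 and 0.25, and mutant library 2, at 0.07, lay above it, against -0.26 and -0.23 in the other mutant libraries. The mitochondrial median was -0.159 with quantile normalization and -0.56 without wild-type library 1 and mutant library 2.

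Immediate early genes, which respond within minutes to stimuli, were shifted up, with 27 of 35 higher, 0 passing adjusted over the list alone and a median log2 fold change of 0.18 (limma adjusted p = 0.00175, and adjusted p = 0.476 with an estimated correlation). Without mutant library 2 the median was 0.122 (adjusted p = 0.229, in a range of 0.000704 to 0.229 over 22 alternatives), and with library weights it was 0.165 (adjusted p = 0.147). The median of immediate early genes was 0.109 without wild-type library 2, 0.111 with genes under a mean of 5 FPKM left out and 0.117 with close pairs summed. The transcription factor genes egr1, nr4a1 and junbb stood at 10.1 ± 0.182 against 6.10 ± 1.01 FPKM, at 3.59 ± 0.687 against 2.04 ± 0.295 and at 40.9 ± 4.45 against 27.6 ± 6.15, and ccn2a, a matricellular protein gene, at 13.7 ± 1.35 against 10.7 ± 0.463. Cell cycle genes were shifted up by a median of 0.11, with 42 of 57 higher and 0 passing adjusted over the list alone (limma adjusted p = 0.0358, and adjusted p = 0.803 with an estimated correlation). This call was lost without mutant library 2 (median 0.041, adjusted p = 0.748), without wild-type library 2 (0.071, adjusted p = 0.107), without wild-type library 3 (0.062, adjusted p = 0.123), with library weights (0.032, adjusted p = 0.254), with the replicate block (adjusted p = 0.0507) and in limma without the variance trend (adjusted p = 0.0561), in a range of 0.00256 to 0.748. Without wild-type library 1 and mutant library 2, the median was 0.145 for immediate early genes (adjusted p = 0.174) and 0.079 for cell cycle genes (adjusted p = 0.231). The cyclins ccna2 and ccnb2 stood at 6.02 ± 0.877 against 3.93 ± 0.744 FPKM and at 2.65 ± 0.497 against 1.70 ± 0.549, the ribonucleotide reductase gene rrm2 at 15.9 ± 4.02 against 10.5 ± 0.957, and esco2 at 6.46 ± 0.739 against 4.55 ± 1.0. The median deviations of mutant library 2 in these lists were 0.17 and 0.16, the highest of the 6 libraries. In the cell cycle list wild-type library 1, at 0.06, lay above mutant libraries 1 and 3, at -0.03 and -0.02, and in the immediate early list it lay at 0.00 against 0.03 and 0.01.

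Among processes that SIRT6 has been tied to, none of the following passed camera in the main test, and some did in alternatives. Genes of glycolysis had a median log2 fold change of 0.05 over 39 genes (adjusted p = 0.465), DNA repair 0.08 over 54 (adjusted p = 0.156), hypoxia response -0.04 over 38 (adjusted p = 0.938), cytosolic ribosomal proteins -0.05 over 76 (adjusted p = 0.446) and insulin, IGF and mTOR signalling 0.01 over 46 (adjusted p = 0.878). Over the alternatives the median ranged from 0.004 to 0.11 for glycolysis, -0.066 to 0.072 for hypoxia response and -0.051 to 0.059 for insulin, IGF and mTOR signalling. The ribosomal list turned direction with the library left out. It passed as shifted up without wild-type library 1 (median 0.218, adjusted p = 0.000302), and as shifted down without wild-type library 2 (-0.108, adjusted p = 0.00463), wild-type library 3 (-0.175, adjusted p = 0.000277) or mutant library 2 (-0.217, adjusted p = 0.00248), in a range of 0.000277 to 0.966. With close pairs summed it also passed as shifted down (-0.072, adjusted p = 0.0495). DNA repair passed as shifted up without wild-type library 1 (0.142, adjusted p = 0.0211) and with the length slope as a covariate (adjusted p = 0.0417), in a range of 0.0211 to 0.741, and glycolysis with that covariate alone (adjusted p = 0.027, in a range of 0.027 to 0.927).

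Targets of inflammation and NF-kB did not pass camera, with a median log2 fold change of 0.07 over 33 genes (adjusted p = 0.0728). They passed as shifted up with genes under a mean of 5 FPKM left out (0.118, adjusted p = 0.00637), with the length slope as a covariate (0.105, adjusted p = 0.0202), and without wild-type library 1 (0.184, adjusted p = 0.021) or mutant library 3 (0.085, adjusted p = 0.0159), in a range of 0.00637 to 0.59. Adjusted over the list alone, irg1l and the complement gene cfb passed as higher and cxcl8a as lower, and fry's test for change in either direction gave an adjusted p of 3.25e-06. For cfb the level was 17 ± 0.843 FPKM against 11 ± 0.815 (SD, n = 3). Genes of cholesterol and fatty acid synthesis had a median of -0.08 over 39 genes (adjusted p = 0.0534). This list passed as shifted down in 11 of 22 alternatives, with medians from -0.112 to -0.053 and adjusted p from 0.0193 to 0.554. These included no filter (adjusted p = 0.0359), genes of a mean of 5 FPKM or more (adjusted p = 0.0437), quantile normalization (adjusted p = 0.035), and the fits without wild-type library 2 (-0.078, adjusted p = 0.0458), wild-type library 3 (-0.106, adjusted p = 0.0258), mutant library 1 (-0.112, adjusted p = 0.0258) or mutant library 3 (-0.078, adjusted p = 0.0204). Over all 36 lists that did not pass, medians ranged from -0.28 to 0.25 and adjusted p from 0.0534 to 0.938. Of these lists, 13 passed in at least 1 alternative and 2, the ribosomal proteins and nuclear-encoded oxidative phosphorylation, in both directions. The oxidative phosphorylation list had a median of 0.185 without wild-type library 1 (adjusted p = 0.000428), of -0.136 without wild-type library 2 (adjusted p = 0.00218), of -0.17 without wild-type library 3 (adjusted p = 0.000471) and of -0.153 without mutant library 2 (adjusted p = 0.00127), in a range of 0.000428 to 0.84.

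**Figure D2:**
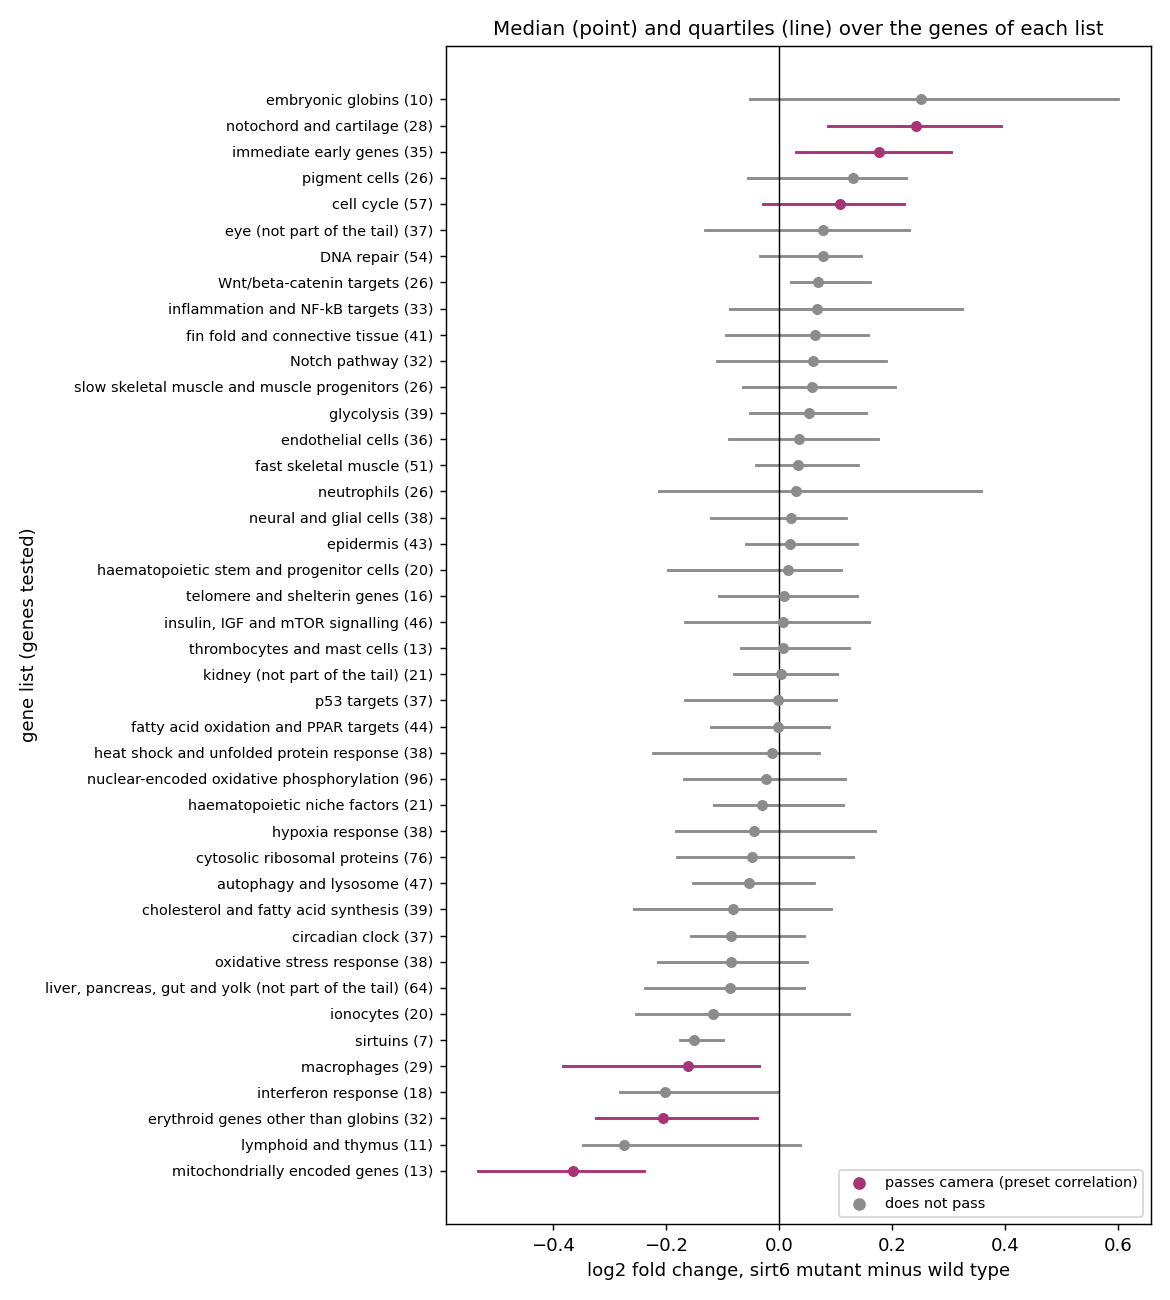
Median (point) and quartiles (line) of the log2 fold change, mutant minus wild type, over the tested genes of each of the 42 lists, with the number of genes in brackets. The 6 lists in colour passed camera at the preset correlation, with medians from -0.37 for mitochondrially encoded genes to 0.24 for notochord and cartilage.

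Libraries labelled as tail held abundant transcripts of organs outside the tail. Of 41 eye genes in the file, 34 were at 1 FPKM or more in all 6 libraries and 12 at 100 or more. The rod pigment gene rho ranged from 284.8 to 909.9 FPKM, the cone pigment gene opn1sw1 from 522.7 to 633.3 and the lens gene crybb1 from 211.9 to 447.9. Of 77 genes of liver, pancreas, gut and yolk, 62 were at 1 FPKM or more in all 6 libraries and 17 at 100 or more, among them the apolipoprotein gene apoa2 at 2835 to 4628 FPKM and the trypsin gene prss1 at 659.1 to 1043. Neither list passed camera between genotypes in the main test, with a median log2 fold change of 0.08 over 37 eye genes (adjusted p = 0.277) and -0.09 over 64 digestive genes (adjusted p = 0.156). The eye list passed as shifted up with quantile normalization (0.103, adjusted p = 0.0167), with the length slope as a covariate (0.148, adjusted p = 0.000929), and without wild-type library 1 (0.235, adjusted p = 0.00543), mutant library 1 (0.094, adjusted p = 0.0492) or mutant library 3 (0.17, adjusted p = 0.0298), in a range of 0.000929 to 0.927. The digestive list passed as shifted down without wild-type library 3 (-0.144, adjusted p = 0.0435) or mutant library 2 (-0.198, adjusted p = 0.00127), in a range of 0.00127 to 0.925. Kidney genes had a median of 0.00 over 21 genes (adjusted p = 0.933). Median deviations of the eye list were 0.21 in wild-type library 1 and 0.29 in mutant library 2, and lay between -0.20 and -0.03 in the others.

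**Figure D3:**
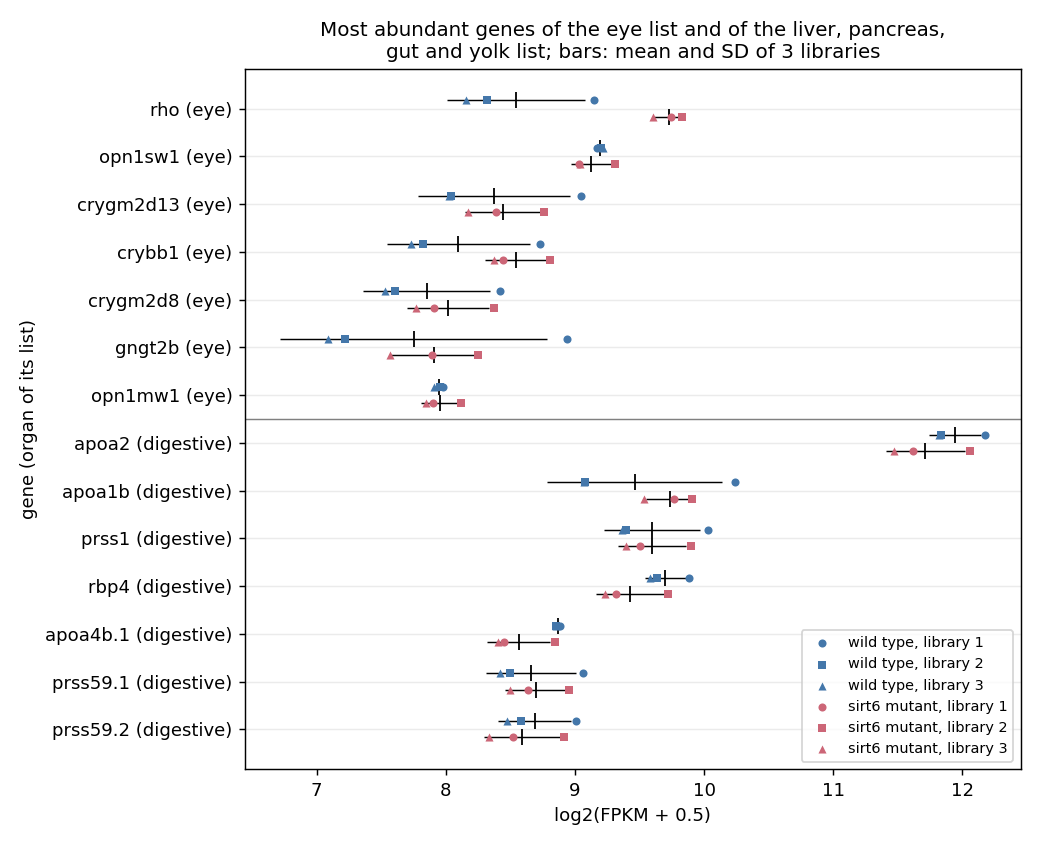
Levels of the 7 most abundant genes of the eye list (upper) and of the liver, pancreas, gut and yolk list (lower), as log2(FPKM + 0.5), with 1 symbol per library and bars for the mean and SD of 3 libraries. All 14 genes were above 100 FPKM in all 6 libraries.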

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

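The alternatives that left out 2 libraries together, weighted libraries, adjusted for gene length, left out alternate contigs or summed close pairs were chosen only after the result was seen. With limma, 0 genes passed in either direction in the alternatives set out beforehand, with 2 exceptions whose cause was not tested. With genes under a mean of 5 FPKM left out 2 passed as higher. With quantile normalization 1 passed as higher (si:ch1073-429i10.1) and 1 as lower (NC_002333.13, a mitochondrial tRNA gene). Another mitochondrial tRNA gene, NC_002333.2, was higher in mutants in the main test (log2 fold change 1.07, limma adjusted p = 0.276). Median-of-ratios rescaling left the limma fit all but unchanged, with 1368 genes of unadjusted p under 0.05 and 6 lists again, so it adds no separate support. Leaving out 1 library gave 0 genes in each direction and between 787 (without wild-type library 2) and 4421 (without wild-type library 1) genes of unadjusted p under 0.05. The added alternatives gave 2183 higher and 2246 lower without wild-type library 1 and mutant library 2, 2295 and 2554 with library weights, 1 and 1 with the length slope as a covariate (rpl36a and NC_002333.13), and 0 and 0 with close pairs summed to 2 against 2 (491 of unadjusted p under 0.05, where chance gives 1193). Whether the replicate numbers pair the libraries was not settled. Same-numbered libraries had deviations that correlated at 0.053, 0.012 and 0.106, and those of unlike number at -0.102 to 0.038. With the replicate block 0 genes passed as higher and 0 as lower, and the sirt6 log2 fold change was -0.114. In that fit 6 lists passed camera, with embryonic globins (adjusted p = 0.0434) in place of the cell cycle list (adjusted p = 0.0507). The sirt6 log2 fold change lay between -0.357 and 0.197 with 1 library left out, was 0.182 without both libraries and 0.137 with weights, and was not tested at a mean of 5 FPKM; the cause of the change in sign is that wild-type library 1 held the highest value. The number of lists passing camera, 6 in the main test, was 9 with no filter and with the stricter filter, 11 with quantile normalization, 8 to 13 with 1 library left out, 2 without both libraries, 3 with weights, 14 with the length slope, 11 with close pairs summed, 0 with an estimated correlation and 1 with fry; the cause was not tested. Of 1079 log2 fold changes of the 50 genes under the naming rule other than sirt6 in the alternatives, 1001 kept direction and side of the threshold, 75 came to pass and 3 changed sign, all of sirt5 (-0.243 to 0.152 with 1 library left out, the sign changing without wild-type library 1, 0.085 without both libraries and 0.105 with weights). The odds ratio of calls on the chromosome of sirt6 had no value, since 0 genes passed. Depth limited genes of few reads, such as dre-mir-92a-2 with 0 to 4.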

Other observations

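Among the tests here, the count of genes of unadjusted p under 0.05 in other splits, the spread and lowest levels of organ markers, the cone comparison, the removal of the length trend, the fit without 2 libraries and its splits, and the tests by chromosome and contig were chosen only after the result was seen. The test on rod genes not looked at before, the anterior organ markers and the ribosomal protein test after length removal were written before their values were seen.

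Rod photoreceptor genes had higher means in mutant libraries, while cone genes went both ways. The first 7 rod genes, noticed from their values, had a median log2 fold change of 0.93, with rho at 849 ± 66.5 FPKM in mutants and 391 ± 154 in wild type (SD, n = 3), although none passed limma over all genes. In 11 further rod genes, 10 were higher and the median was 0.422 (95% bootstrap interval 0.253 to 0.54 over genes, which are not independent), in line with a shift shared by rod genes, and it lay between 0.32 and 0.531 with 1 library left out. The highest of these medians came without mutant library 2. In that library cngb1a, at 3.55 FPKM, and cnga1b, at 1.57, lay below all wild-type libraries (3.84 to 5.16 and 1.59 to 1.94). Others of the further rod genes, such as pde6a at 3.7 against 2.22 to 2.71, lay above them. Over 17 cone genes the median was -0.015 (-0.119 to 0.154), which argues against more eye tissue in mutant libraries as the whole source. What stays open is a difference in rod number or timing, in developmental age between the groups, or in a pool or preparation shared within the close pairs, none of which was tested. With 10 splits of 6 libraries chance cannot be given a share under 0.1. The genotype split gave 0.422 and the highest other 0.305.

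Transcripts of the eye and digestive organs in libraries labelled as tail may reflect RNA from outside the tail. Over 101 eye and digestive markers, the median ratio of the lowest library to the highest was 0.61 (95% bootstrap interval 0.55 to 0.64), which argues against tissue carried over into single libraries as the only source. A larger share in wild-type library 1 and mutant library 2 stays open, since the markers' median SD was 1.19 times that of genes of like level (1.09 to 1.43), and the eye list deviated by 0.214 and 0.291 there against -0.198 to -0.026 in the others, and the digestive list by 0.177 and 0.167 against -0.158 to -0.024. The same libraries carried more reads of short genes. Cytosolic ribosomal proteins deviated there by 0.593 and 0.291, and nuclear-encoded oxidative phosphorylation by 0.516 and 0.27. The deviations of the organ lists thus cannot tell a larger share of organ RNA from this wider difference between libraries. Of 29 markers of heart, pituitary, forebrain and midbrain, ear, thyroid and nose, 58.6% were at 1 FPKM or more in all 6 libraries, between the limits set for and against RNA of anterior organs throughout, among them all 8 forebrain and midbrain genes, 1 of 6 pituitary and 0 of 3 thyroid genes, the ear gene stm at 47.4 to 78.7 FPKM and the heart gene myl7 at 13.7 to 23.1. How many of these genes the tail also expresses was not tested, and no library of another body part was analysed here. The eye is not part of the tail, yet 34 of 41 eye genes were at 1 FPKM or more in all 6 libraries. Of these, 12 were at 100 or more, which argues against tail tissue as the only source of the eye transcripts. How the other RNA entered the libraries stays open.

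Wild-type library 1 and mutant library 2 stood apart from the other 4, and without them 4429 genes passed limma, 3525 of which also passed with library weights. The weights gave these 2 libraries the lowest values, 0.223 and 0.263, so these fits are not independent of each other. Once a smooth length trend was removed 0 genes passed limma on all 6 libraries and 1546 had an unadjusted p under 0.05, against 0 and 1368 before the removal, which says nothing on a gene-length trend as the cause, and part of the trend remained in wild-type library 1, with a slope of -0.14 before and -0.05 after. After that removal, ribosomal protein genes still deviated by 0.543 in wild-type library 1 and 0.244 in mutant library 2, and by -0.283 to -0.093 in the others, in line with a difference in these transcripts apart from length. The 4 remaining libraries are the 2 close pairs, so their genotype split is also the split between pairs. A shared pool or preparation within each pair may thus account for calls among the 4 as well as genotype does, and neither this nor a part for gene length was decided.

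With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The genotype split gave 0 genes passing limma and the highest other split 2, and 10 of the 10 splits gave as many. Since any split gives at least 0, that count of splits decides nothing. At an unadjusted p under 0.05 the genotype split gave 1368 genes, the highest other 4216, and 5 splits gave as many. The split of highest count set wild-type libraries 2 and 3 with mutant library 2 against the rest, which points to a structure of the samples. It keeps wild-type libraries 2 and 3 apart from mutant libraries 1 and 3, so it does not separate genotype from the close pairs. Of the 3 splits of these 4 libraries, that by genotype gave 4429 genes passing limma and the others 0, with 287 and 260 at an unadjusted p under 0.05. For lists passing camera, the genotype split of all 6 libraries gave 6, the highest other split 17, and 5 of the 10 splits gave as many.

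Of the genes with an unadjusted p under 0.01, 21 of 224 on primary contigs lay on chromosome 2, which holds sirt6, an odds ratio of 1.97 (95% interval 1.19 to 3.11, Fisher's exact test adjusted over chromosomes p = 0.135), and the highest other split gave 2.44 (0.62 to 6.92). On alternate contigs lay 72 of 296 such genes, an odds ratio of 2.1 (1.58 to 2.75), and the highest other split gave 2.83 (1.61 to 4.83). Within 5 Mb of sirt6, 5 of 156 genes had an unadjusted limma p under 0.01, against 296 of all 23855. On chromosome 2, saga, MFN1 and an unnamed gene lay between 5321905 and 5505094 and were all higher (log2 fold change 1.215, 1.374 and 1.069). An unnamed gene at 4375255 and scp2a at 6005199 were lower (-0.748 and -0.458). Whether position plays a part in saga was not tested.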
